A study of Mus musculus with 6 samples.

How the data were processed

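The series holds 6 single-cell libraries, 1 per mouse, from orthotopic pancreatic tumours of 3 WT and 3 Lin28bKO hosts of mixed sex. The labels give hosts aged 6 to 8 weeks, 30 min of digestion and the 10x 3′ kit of version 3. The deposited values are raw UMI counts per gene and cell barcode, and per the labels they were made by the authors with Cell Ranger 7.1.0 on mm10 (GRCm38), with Seurat named beside it. The file headers give Cell Ranger 7.0.0. Of 55357 gene identifiers, 52081 are in the GENCODE M21 annotation of GRCm38 and 3276 (5.92%) are not, of which 2142 have the newer identifier form, so the annotation used for counting is not given in the sources used here. Positions were taken from M21. The files hold called cell barcodes only, and the lowest UMI count per barcode differed between libraries.

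Cells were kept with at least 500 UMIs, at least 250 genes and at most 15% of UMIs from mitochondrial genes. More than 15% was found in 22.9, 13.2 and 17.5% of barcodes in WT replicates 1, 2 and 3 and in 3.14, 4.64 and 7.24% in Lin28bKO replicates 1, 2 and 3. Doublets were scored with Scrublet in scanpy per library, and the highest scores were removed at 0.8% per 1000 barcodes, which took 7367 cells and left 61478 of 77684 barcodes. Counts per 10000 were log-transformed, 2000 variable genes, 30 principal components and 15 neighbours were used, and clusters were found with Leiden at resolution 1.0 without integration of libraries. Clusters were named "-like" after the nearest of 18 fixed marker lists. A cluster stayed unnamed, and is given by number, when fewer than 3 markers of that list were detected or another list had more markers among its top 10 genes. It also stayed unnamed when its UMIs were low and no marker of the nearest list was among these 10. In the tumour-like class, clusters 0 to 5 had 0 markers of their list among the top 10 genes, so their names do not rest on leading genes. T and natural killer cells were clustered again and named from 6 fixed lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.

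UMIs were summed per class and library, and the mouse was the replicate throughout. A class was tested when every library gave it at least 30 cells, which held for 10 classes and for the whole tumour. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 after its filter on low counts, with TMM scaling, and p was adjusted by Benjamini-Hochberg within each class with a threshold of 0.05. CPM of Lin28b, Lin28a, Xist, Y-linked genes and acinar enzyme genes, and of S100a4 with doublets kept, are scaled by the UMI total alone. Other CPM are TMM-scaled. Numbers of cells per class were tested with edgeR and with an exact permutation test. The 30 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with the preset correlation 0.01, with camera under an estimated correlation, and with fry, in the whole tumour and in 8 classes (not in clusters 7 and 12), where at least 5 members passed the filter. Members adjusted over the list alone come from the same edgeR p. The genotype effect was compared with a term for the mouse between the 3 classes with most cells, and between neutrophil-like cells and the 2 named classes among these, a choice added later. Marker lists, gene lists, tests and the alternatives were fixed before the data were examined, except for those named as added.

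Genes were to be named when they passed the adjusted threshold with at least 20 CPM and no overlap. None did, so by the fixed rule the 5 genes with the smallest p in each class are given as values, with Lin28b, Lin28a, S100a4, the let-7 targets and up to 4 members of each called list, the ones with the smallest p. Markers of other classes, antigen receptor segments, haemoglobins, sex-linked and mitochondrial genes and unnamed gene models were left out of that ranking.

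Free RNA was measured with 42 genes at 100 CPM or more in tumour-like cells, chosen after the data were seen. They were at least 5 times their level in macrophage-like, neutrophil-like, T cell-like, conventional dendritic-like and plasma cell-like cells. They were not required to be lower in stromal cells, and took 0.536% of fibroblast-like and 1.76% of tumour-like UMIs in WT. Their share of a class's UMIs, over their share in tumour-like cells, gave the number of Lin28b UMIs due to free RNA. On simulated data with the spread of each class, edgeR called 30 to 62 of 66 genes changed 4-fold and 0 to 30 of 67 changed 2-fold, with 2 to 11 false calls, while DESeq2 made up to 52 false calls among 140 in the whole tumour. A 2-fold shift of the interferon-gamma list had an unadjusted p = 0.00290 by camera with an estimated correlation in the simulated whole tumour. The preset correlation called 0 of 24 unmoved lists there. A split of the real libraries that mixed WT and Lin28bKO called 107 lists over the groups tested. The simulation did not reproduce this, so that p does not show the power of the test in the real data. An 8-fold change in a share was found in 82% of draws simulated at a dispersion of 0.3.

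The alternatives were DESeq2 1.42.0, the size factors of DESeq2, no filter on low counts, the replicate number of the titles as a block, leaving out each library in turn, doublets kept, at least 500 genes with at most 10% mitochondrial UMIs, the Y-linked sum as a covariate, Leiden resolutions 0.5 and 2.0, other classes' markers left out, and immune cells as denominator. Those added after seeing the data were a common floor of 2200 UMIs, a floor relative to each library's macrophage-like cells, a denominator without unnamed clusters, and, for the comparison between classes, leaving out Lin28bKO replicate 1, genes that passed in both classes, and limma. Intronic reads, splicing and variants were not analysed here. Classes with fewer cells were left untested for genes.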

Results

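Single-cell RNA was counted in orthotopic pancreatic tumours from 3 wild-type mice (WT) and 3 Fsp-Cre;Lin28bfl/fl mice (Lin28bKO), 1 library per mouse. All hosts had received 50000 cells of the pancreatic tumour line 15376T, so the deletion concerned host cells that use the Fsp promoter and not the injected cells. The deposited matrices held 12665, 14062 and 12043 cell barcodes with 119567457, 229017730 and 107998904 UMIs in WT replicates 1, 2 and 3. Lin28bKO replicates 1, 2 and 3 held 14305, 13219 and 11390 barcodes with 114738464, 116400648 and 123342257 UMIs. After filtering, 28453 WT cells and 33025 Lin28bKO cells remained. Their median UMI count per library was 5370.5 to 8442.5 in WT and 5122 to 8275 in Lin28bKO. Within classes named below the depth differed more: tumour-like medians were 18872.5, 34640 and 19331 UMIs in WT and 7539, 10099.5 and 15561.5 in Lin28bKO. The mean UMIs per cell in Lin28bKO over WT were 0.508 in tumour-like, 0.607 in macrophage-like and 0.482 in conventional dendritic-like (cDC-like) cells. Errors are SD between mice with n = 3 per group unless stated, and tests are two-sided. The p of edgeR and of the permutation test measure the spread between mice. Camera with the preset correlation takes the members of a list as nearly independent, so its p and its calls do not measure that spread. An exact permutation test of 3 mice against 3 cannot give a p below 0.1. Fold changes are log2 of Lin28bKO over WT.

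The first comparison concerned the targeted gene and the locus whose promoter drives Cre. Lin28b encodes an RNA-binding protein that blocks the maturation of let-7 microRNAs. Its UMIs came mainly from the tumour-like cells, which gave 1221 of 1288 in WT and 1044 of 1153 in Lin28bKO. In the 5 libraries with Y-linked transcripts, tumour-like cells had 1.18 to 2.80 CPM of them and macrophage-like cells 145 to 177, while tumour-like cells had 1224 to 1775 CPM of Xist, the X-inactivation RNA of female cells, in all 6. S100a4, the calcium-binding protein also called Fsp, took its largest share of UMIs, among the classes tested, in the macrophage-like, T cell-like and cDC-like classes.

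Lin28b (ENSMUSG00000063804) lies on chromosome 10 from 45376620 to 45486395 on the minus strand of GRCm38. In the whole tumour it averaged 3.36 ± 0.862 CPM in WT and 3.74 ± 1.28 in Lin28bKO. The fold change was 0.14 (SE 0.30, edgeR adjusted p = 0.958). In tumour-like cells it averaged 4.52 ± 1.53 CPM in WT and 4.29 ± 1.42 in Lin28bKO, a fold change of -0.07 (SE 0.30, adjusted p = 1.00). Host classes held few Lin28b UMIs. Macrophage-like cells had 11 in WT, where free RNA from tumour cells would give 13.7, and 19 in Lin28bKO, where it would give 8.70. Neutrophil-like cells had 10 against 6.06 in WT and 3 against 1.36 in Lin28bKO, and T cell-like cells had 4 against 1.16 and 0 against 1.27. Of the 19 macrophage-like UMIs in Lin28bKO, 12 came from replicate 1. The part of Lin28b between the loxP sites is not given in the sources used here, and 3′ tags need not lie in it, so these counts do not test the deletion.

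S100a4 (ENSMUSG00000001020) lies on chromosome 3 from 90603771 to 90606045. Scaled by TMM, it averaged 547 ± 29.1 CPM in WT and 353 ± 55.7 in Lin28bKO macrophage-like cells, a fold change of -0.63 (SE 0.15, adjusted p = 0.258). In T cell-like cells it averaged 761 ± 19.8 and 500 ± 66.7 CPM, a fold change of -0.61 (SE 0.18, adjusted p = 0.379). Dendritic-like cells had 923 ± 170 and 661 ± 76.7 CPM. The 3 WT values lay above the 3 Lin28bKO values in each of these classes, and none of the adjusted p passed. Fibroblast-like cells had 112 ± 41.6 and 62.7 ± 32.6 CPM, and tumour-like cells had 174 ± 56.5 and 151 ± 13.3 CPM, both with overlap.

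The title of the series names immune modulation, so the composition of the tumours was compared next. Neutrophil-like cells made up 16.8% ± 4.98 of the WT cells and 3.19% ± 2.97 of the Lin28bKO cells. Macrophage-like cells made up 18.2% ± 4.53 and 10.8% ± 2.30. Tumour-like cells made up 37.2% ± 5.53 in WT and 57.9% ± 3.77 in Lin28bKO. In each of these 3 classes the mice of the 2 groups did not overlap, the most that an exact permutation test can show here (p = 0.1). These are shares of the cells kept. The tumour-like share leaves out unnamed clusters 7 and 12, although the tumour-like list was the nearest for both. Cluster 12 held 4330 WT and 3252 Lin28bKO cells. The 42 tumour-enriched genes took 1.18% of its UMIs in WT and 1.27% in Lin28bKO. They took 1.76% and 1.74% in tumour-like cells and 0.536% and 0.662% in fibroblast-like cells. A tumour-like share with these clusters counted in was not tested. The limit on mitochondrial UMIs was exceeded by 13.2 to 22.9% of barcodes in WT and 3.14 to 7.24% in Lin28bKO. Shares without that limit were not tested. T cell-like cells made up 3.03% ± 0.815 and 2.17% ± 1.31, with overlap (exact permutation p = 0.4).

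**Figure D1:**
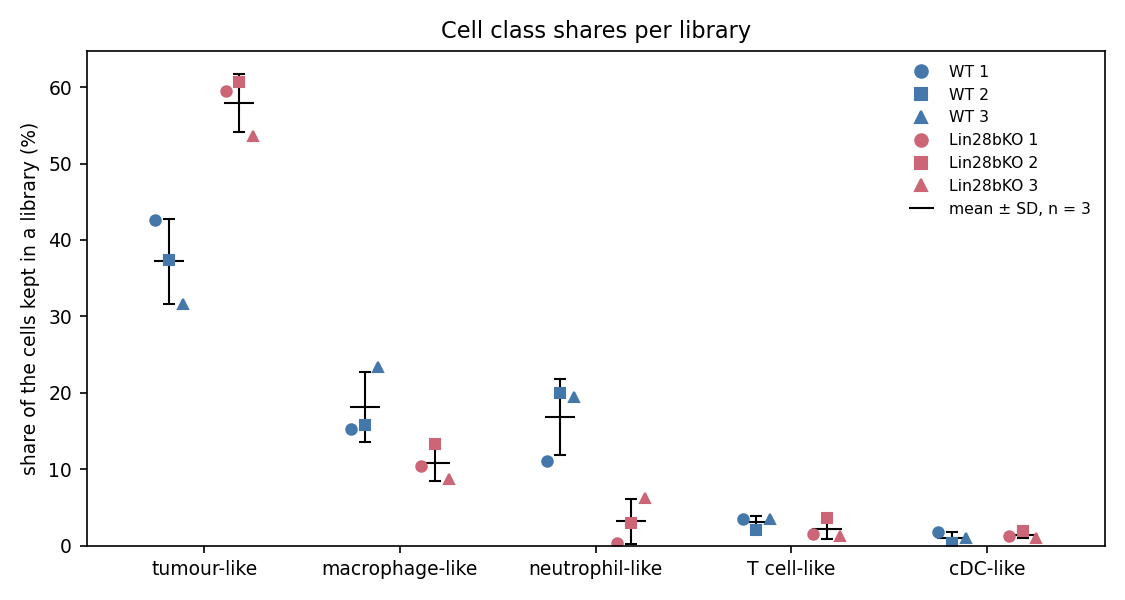
Share of kept cells (%) in 5 classes, with a point per library and the mean ± SD of 3 mice. Neutrophil-like shares were 11.1, 19.9 and 19.5% in WT and 0.352, 2.93 and 6.27% in Lin28bKO, and tumour-like shares were higher in every Lin28bKO library than in every WT library.

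By edgeR on cell numbers, 0 of 20 classes passed an adjusted p of 0.05. In data simulated at a dispersion of 0.3 over 20 classes a 4-fold change in a share was called in 43.5% of draws. That setting is not the spread of each single class. The fold change was -2.40 for neutrophil-like cells (SE 1.03, adjusted p = 0.626), -0.75 for macrophage-like cells (SE 0.52, adjusted p = 0.639) and 0.64 for tumour-like cells (SE 0.49, adjusted p = 0.639). Neutrophil-like cells had a median of 1398 to 2786 UMIs per library, while the lowest UMI count of any deposited barcode was 658 to 780 in WT and 2174, 1302 and 857 in Lin28bKO replicates 1, 2 and 3. With a floor set in each library at the same multiple of its median macrophage-like UMI count, neutrophil-like cells made up 3.24% ± 2.86 and 0.985% ± 0.904, with overlap (exact permutation p = 0.2). Tumour-like shares overlapped under both floors: 53.7% and 70.7% under a common floor of 2200 UMIs (fold change 0.40) and 54.6% and 64.8% under the relative floor (0.25), each with an exact permutation p = 0.2. T cell-like shares were 4.63% and 1.96% under the common floor, without overlap (fold change -1.24, exact permutation p = 0.1). That floor came with a new clustering, which gave no natural killer-like class. Its T cell-like class held 354 cells in WT replicate 1, against 302 over all kept cells, where the fold change was -0.48. These fold changes are thus not for the same class. Under the relative floor T cell-like shares were 2.87% and 1.81%, with overlap (exact permutation p = 0.3). Among immune cells alone, neutrophil-like cells made up 40.6% and 15.6% (fold change -1.38), and macrophage-like cells turned to a fold change of 0.30.

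Several smaller groups came mainly from 1 mouse. Lin28bKO replicate 1 gave 240 of 302 mast and basophil-like cells, 1545 of 1977 cells of unnamed cluster 7 and 391 of 540 cells of unnamed cluster 24. Erythroid-like cells came mostly from Lin28bKO replicate 3, with 156 of 207. Among immune cells alone, cDC-like cells made up 2.65% ± 2.21 in WT and 6.97% ± 1.33 in Lin28bKO, without overlap (exact permutation p = 0.1, edgeR adjusted p = 0.366). Among all cells they made up 1.02% ± 0.701 and 1.42% ± 0.455, with overlap (exact permutation p = 0.4).

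Lymphocytes were then clustered alone. Regulatory T-like cells, which restrain immune responses, made up 4.26% ± 1.05 of lymphocytes in WT and 8.63% ± 1.39 in Lin28bKO, without overlap between the mice (131 cells). The fold change was 0.99 (SE 0.39, edgeR adjusted p = 0.195, exact permutation p = 0.1). Natural killer-like cells made up 18.0% ± 0.308 and 13.3% ± 4.50, CD8 T-like cells 39.4% ± 12.9 and 42.7% ± 16.8, and CD4 conventional T-like cells 33.7% ± 8.97 and 28.3% ± 9.70, all with overlap. Of 6 groups, 0 passed edgeR, and 1 had an unadjusted p below 0.05.

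In the whole tumour, all kept cells summed, transcripts typical of myeloid cells were lower in Lin28bKO. All 17 tumour-associated neutrophil genes were lower (median fold change -1.28; adjusted p = 0.678 with an estimated correlation), and 12 of them passed when adjusted over the list alone. The neutrophil chemoattractant Cxcl2 averaged 1021 ± 370 CPM in WT and 282 ± 66.4 in Lin28bKO, and the chemokine Ccl3 had a fold change of -1.49 (SE 0.26). Il1b, a pyrogenic cytokine, averaged 622 ± 261 and 253 ± 29.6 CPM, and the immune-cell adaptors Fcer1g and Tyrobp averaged 424 and 376 CPM in WT and 190 and 180 in Lin28bKO. These sums follow cell composition as well as expression per cell.

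Camera with the preset correlation called the tumour-associated neutrophil list at an adjusted p = 5.67e-13. It also called the NF-kB inflammatory genes (17 of 17 lower, median -0.79), the complement and phagocytosis genes (14 of 15 lower, -0.75) and the monocyte genes (9 of 10 lower, -1.33), each lower and each with an adjusted p = 0.678 with an estimated correlation. The interferon-gamma response genes were lower as well (17 of 17, median -1.42, 11 passed adjusted over the list alone; adjusted p = 0.678 with an estimated correlation), and without WT replicate 3 their median was -0.83, still called. Among single genes, edgeR called 0 of 19835 in the whole tumour, with 1591 at an unadjusted p below 0.05, and DESeq2 called 447, of which 433 were lower. Without WT replicate 1, edgeR called 6. Groups did not overlap for 13.3% of genes, where chance gives 10%. The genes with the smallest p were Slc6a13 (-2.09), F5 (-1.48), Il36g (-2.78), Olr1 (-1.80) and Slfn1 (-1.78), each with an adjusted p = 0.326. Il36g, an epithelial cytokine of the interleukin-1 family, averaged 12.4 ± 5.38 and 1.81 ± 0.443 CPM. Olr1, a scavenger receptor, averaged 10.9 ± 2.49 and 3.13 ± 0.718 CPM.

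In tumour-like cells interferon response genes were lower in Lin28bKO hosts. The class joined several clusters. Cluster 3, led by Ifi44 and Iigp1, gave 17.6% of the class's cells in WT and 9.34% in Lin28bKO with the mice pooled. Per library it gave 669 of 3724, 404 of 4029 and 788 of 2819 cells in WT replicates 1, 2 and 3. In Lin28bKO replicates 1, 2 and 3 it gave 672 of 7274, 899 of 6820 and 223 of 5120, so the groups overlapped. The values of the class follow that composition too. All 17 interferon-gamma response genes had a lower mean (median fold change -1.19; adjusted p = 0.678 with an estimated correlation), and 2 passed adjusted over the list alone. The interferon-induced GTPases Iigp1, Gbp2 and Tgtp1 averaged 173 ± 120, 231 ± 168 and 20.1 ± 8.57 CPM in WT and 51.2 ± 26.8, 77.8 ± 30.4 and 6.78 ± 2.70 in Lin28bKO. Type I interferon response genes (20 of 20 lower, median -0.41) and MHC class I presentation genes (17 of 17 lower, median -0.34) went the same way, each with an adjusted p = 0.678 with an estimated correlation. Of the matrix and contractile lists, 23 of 24 extracellular matrix genes (median 0.33) and 14 of 14 myofibroblastic genes (median 0.73) were higher, each list with an adjusted p = 0.678 with an estimated correlation.

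Camera with the preset correlation called these 5 lists, the interferon-gamma list at an adjusted p = 2.78e-14. WT replicate 3 weighed most: without it the interferon-gamma median was -0.52, with the camera call kept. That library was also the only one with almost no Y-linked transcripts, 0.0754 CPM for Ddx3y, Eif2s3y, Kdm5d and Uty together against 21.6 to 35.0 CPM in the other 5. With the Y-linked sum as a covariate the median was -0.62. Cell cycle genes were higher (21 of 22, median 0.28; adjusted p = 0.725 with an estimated correlation). Among single genes edgeR called 0 of 17706, with 347 at an unadjusted p below 0.05 and 5.98% without overlap (chance gives 10%), and DESeq2 called 1. The smallest p belonged to Ptn, a heparin-binding growth factor near 0 CPM here (0.0345 and 0.228), Cavin4, Mgmt, Rps2-ps10 and the non-coding Snhg6 (133 ± 9.71 and 93.9 ± 6.66 CPM), each with an adjusted p = 1.00.

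**Figure D2:**
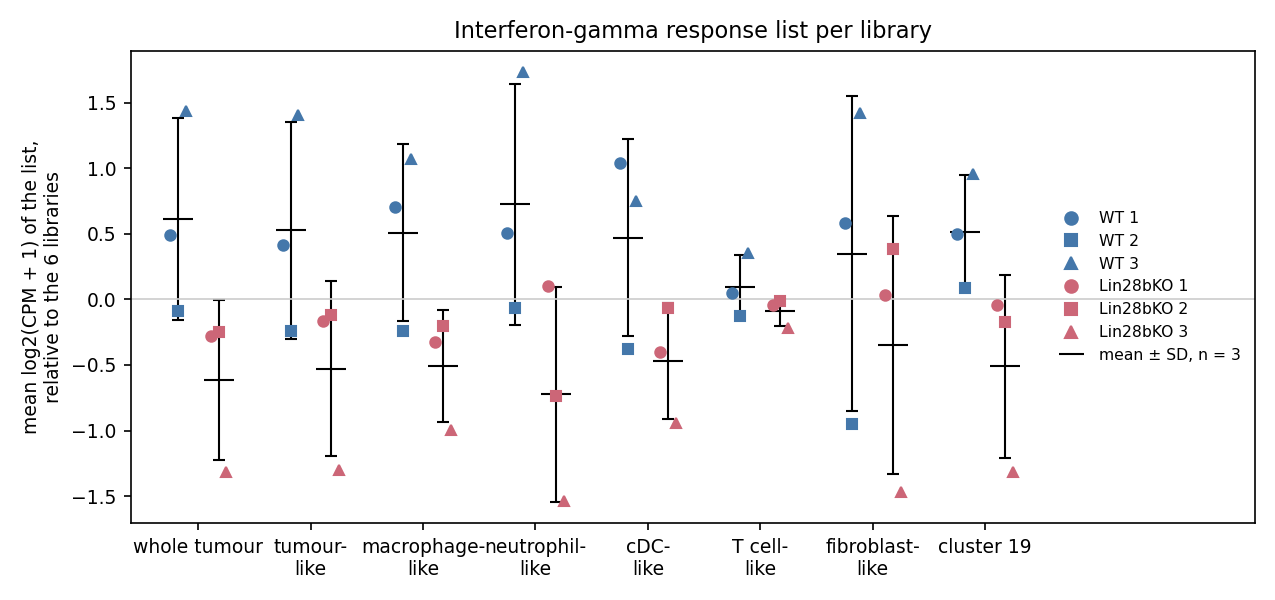
Mean log2(CPM + 1) of the interferon-gamma response list per library, relative to the mean of the 6 libraries, for the whole tumour and 7 classes, with the mean ± SD of 3 mice. In tumour-like cells WT replicates 1, 2 and 3 sat at 0.42, -0.24 and 1.40 and the Lin28bKO replicates at -0.16, -0.12 and -1.30, so WT replicate 2 lay within the Lin28bKO range.

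In macrophage-like cells the same interferon genes were lower, and cell cycle genes were higher. All 16 interferon-gamma genes measured had a lower mean (median -1.06; adjusted p = 0.678 with an estimated correlation), and 9 passed adjusted over the list alone. Iigp1 averaged 176 ± 56.1 CPM in WT and 52.9 ± 24.4 in Lin28bKO, and Gbp2 averaged 463 ± 232 and 155 ± 43.2. The monocyte genes were lower in 10 of 10 (median -0.92; adjusted p = 0.678 with an estimated correlation), and hypoxia and glycolysis genes in 18 of 19 (median -0.27; adjusted p = 0.725 with an estimated correlation). Of 22 cell cycle genes 21 were higher (median 0.95; adjusted p = 0.678 with an estimated correlation), among them the spindle factor Tpx2 at 11.6 ± 1.42 and 23.9 ± 11.1 CPM.

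Camera with the preset correlation called these lists. Without WT replicate 3 the interferon-gamma median was -0.66, still called. EdgeR called 0 of 12391 single genes, with 1336 at an unadjusted p below 0.05 and 15.9% without overlap (chance gives 10%). DESeq2 called 157, and without Lin28bKO replicate 2 edgeR called 66. Hopx, a homeodomain-only protein, averaged 59.1 ± 15.8 and 21.4 ± 1.54 CPM (-1.47, adjusted p = 0.229), and the kinase Lrrk2 averaged 16.2 ± 1.36 and 6.61 ± 0.386 (-1.29, adjusted p = 0.198). Tbc1d4 and Mical2 were at 5.32 and 3.78 CPM in WT and 13.4 and 9.11 in Lin28bKO. Lamb1, a laminin chain, averaged 14.2 ± 0.486 and 31.1 ± 2.05 CPM here and 252 and 266 in tumour-like cells. Transcripts of 42 genes enriched in tumour-like cells took 0.116% ± 0.0184 of macrophage-like UMIs in WT and 0.188% ± 0.0148 in Lin28bKO. Epithelial identity genes were higher with them (5 of 5, median 0.90; adjusted p = 0.678 with an estimated correlation).

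**Figure D3:**
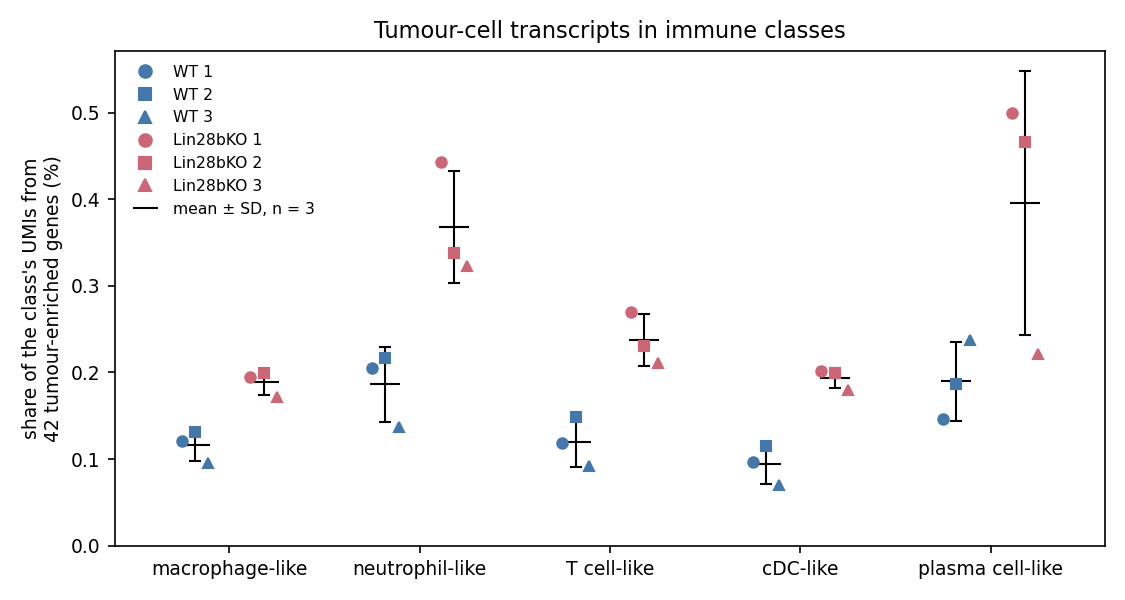
Share of each immune class's UMIs (%) from 42 genes enriched in tumour-like cells, with a point per library and the mean ± SD of 3 mice. The Lin28bKO values lay above all WT values in macrophage-like (1.63-fold in the mean), neutrophil-like (1.98-fold), T cell-like (1.98-fold) and cDC-like cells (2.06-fold), and overlapped them in plasma cell-like cells.

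Neutrophil-like cells, 43 to 2149 per library, had lower interferon and higher cell cycle transcripts in Lin28bKO. The class joined clusters 16 and 17. With the mice pooled, cluster 17, led by Ngp, Camp and Ltf, gave 43 of the class's cells in WT (0.885%) and 46 in Lin28bKO (4.73%). The values of the class thus follow that composition too. All 15 interferon-gamma genes measured were lower (median -1.58; adjusted p = 0.678 with an estimated correlation), and 14 passed adjusted over the list alone. Cd274, the checkpoint ligand PD-L1, averaged 867 ± 385 CPM in WT and 327 ± 86.5 in Lin28bKO, and the T cell chemoattractant Cxcl9 averaged 82.5 ± 88.1 and 9.12 ± 5.29. Of 17 tumour-associated neutrophil genes 16 were lower (median -0.64; adjusted p = 0.678 with an estimated correlation), including Hilpda, an inhibitor of lipid breakdown, at 1322 ± 220 and 482 ± 248 CPM, and Cxcl2 at 25338 ± 2982 and 13637 ± 4232 CPM. Cell cycle genes were higher in 20 of 21 (median 1.20; adjusted p = 0.678 with an estimated correlation), and 11 passed adjusted over the list alone.

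Besides these lists, camera with the preset correlation called hypoxia and glycolysis (17 of 18 lower, median -0.42, adjusted p = 0.678 with an estimated correlation). Without WT replicate 3 the interferon-gamma median was -1.04, still called. Top2a and Ube2c, which act in mitosis, averaged 35.2 and 20.4 CPM in WT and 101 and 51.4 in Lin28bKO, against 173 to 217 and 95.9 to 124 in tumour-like cells, and the 42 tumour-enriched genes took 0.186% ± 0.0434 and 0.368% ± 0.0651 of the UMIs here. Among single genes edgeR called 0 of 8161, with 1882 at an unadjusted p below 0.05 and 29.8% without overlap (chance gives 10%), and DESeq2 called 179, of which 159 were lower. The smallest p belonged to Fnip2 (173 ± 12.2 and 57.7 ± 11.1 CPM), AI839979, Hgsnat (149 ± 16.1 and 53.0 ± 13.6 CPM), Cldn1 and the glycolytic regulator Pfkfb3 (164 and 61.1 CPM), each lower with an adjusted p = 0.127.

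In T cell-like cells the mean levels of cytotoxic transcripts were lower and that of the regulatory T cell factor Foxp3 was higher, without a single gene past the threshold. The class holds the regulatory T-like cells, whose share of lymphocytes was 4.26% and 8.63%, so its sums follow composition as well as expression per cell. Gzmb, the killing protease granzyme B, averaged 787 ± 163 CPM in WT and 346 ± 39.4 in Lin28bKO (-1.18, SE 0.20, adjusted p = 0.160). Foxp3 averaged 33.2 ± 12.0 and 89.5 ± 16.9 CPM (1.44, SE 0.27, adjusted p = 0.160). Of 15 cytotoxic effector genes 13 were lower (median -0.38; adjusted p = 0.678 with an estimated correlation), and 8 passed adjusted over the list alone. Gzma averaged 238 ± 48.5 and 130 ± 41.8 CPM and the pore-forming Prf1 117 ± 32.0 and 67.4 ± 37.4, while Klrg1, an inhibitory receptor, averaged 30.6 ± 11.1 and 60.1 ± 11.2.

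**Figure D4:**
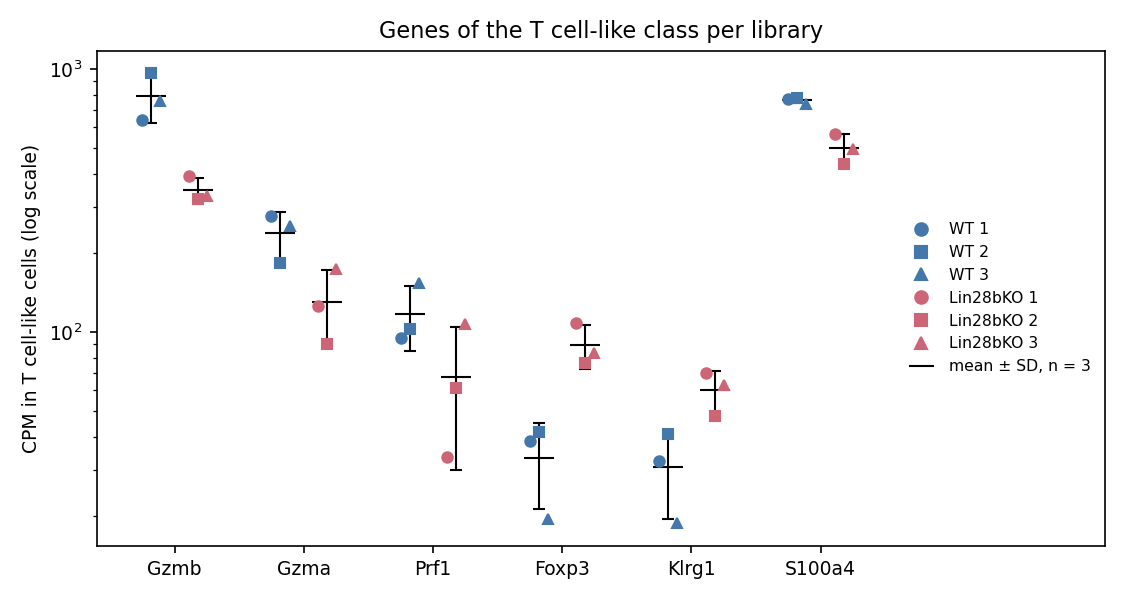
CPM in T cell-like cells (log axis) of Gzmb, Gzma, Prf1, Foxp3, Klrg1 and S100a4 per library, with the mean ± SD of 3 mice. The groups did not overlap for any of them except Prf1, with Gzmb at 787 and 346 and Foxp3 at 33.2 and 89.5 in WT and Lin28bKO.

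Camera with the preset correlation called that list and the T cell exhaustion list (10 of 11 lower, median -0.30; adjusted p = 0.678 with an estimated correlation). Type I interferon response genes were lower in 17 of 18 (median -0.44, 3 passed adjusted over the list alone, adjusted p = 0.678 with an estimated correlation), with the antiviral Mx1 at 37.4 ± 4.28 and 16.6 ± 7.67 CPM. The interferon-gamma list was not called here (11 of 13 lower, median -0.20, adjusted p = 0.0676; median -0.06 without WT replicate 3), nor were the regulatory T cell genes (7 of 12 higher, median 0.17) or the naive and memory genes (5 of 10 higher). Cell cycle genes were higher in 20 of 21 (median 0.75; adjusted p = 0.678 with an estimated correlation), with Ube2c at 39.4 ± 12.2 and 98.3 ± 55.1 CPM. Among single genes edgeR called 0 of 8573, with 613 at an unadjusted p below 0.05 and 12.3% without overlap (chance gives 10%). DESeq2 called 15, and without Lin28bKO replicate 1 edgeR called 6. Sox4, Nedd4 and Cdkn2a were also among the smallest p, at 57.8, 54.3 and 32.1 CPM in WT and 128, 127 and 73.1 in Lin28bKO. All 3 are abundant in tumour-like cells (544 to 1089 CPM), whose 42 enriched genes took 0.120% ± 0.0289 and 0.238% ± 0.0300 of T cell-like UMIs.

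In cDC-like cells all 15 interferon-gamma genes measured were lower (median -1.03; adjusted p = 0.678 with an estimated correlation), and 6 passed adjusted over the list alone. Iigp1 averaged 110 ± 49.1 CPM in WT and 24.1 ± 9.26 in Lin28bKO (-2.18, adjusted p = 0.240). The interferon-induced chemokines Cxcl11 and Cxcl9 averaged 94.1 ± 59.2 and 520 ± 157 CPM in WT and 12.4 ± 3.69 and 166 ± 101 in Lin28bKO. Irf7, a driver of interferon transcription, averaged 91.0 ± 5.17 and 40.7 ± 19.7 CPM. Camera with the preset correlation called the list, and without WT replicate 1 the median was -0.56, still called. The growth factor Mdk, Nedd4 and Cavin1 averaged 19.6, 31.8 and 12.6 CPM in WT and 54.2, 76.0 and 40.0 in Lin28bKO. All are abundant in tumour-like cells (211 to 623 CPM), whose enriched transcripts were 2.06-fold higher here. Among single genes edgeR called 0 of 7452, with 402 at an unadjusted p below 0.05 and 10.8% without overlap (chance gives 10%). DESeq2 called 2, and without WT replicate 2 edgeR called 2.

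Fibroblast-like cells, 39 to 192 per library, had more Ptn, at 88.3 ± 1.15 CPM in WT and 238 ± 33.1 in Lin28bKO (1.43, adjusted p = 0.868). The matrix protein Tnn averaged 8.94 ± 1.10 and 1.55 ± 0.317 CPM, Acsbg1 5.07 and 17.3, Cpxm2 9.66 and 24.4, and the adrenergic receptor Adra2a 0.734 and 13.3. Cell cycle genes were lower in 20 of 22 (median -0.45; adjusted p = 0.678 with an estimated correlation), and inflammatory fibroblast genes in 12 of 18 (median -0.28; adjusted p = 0.678 with an estimated correlation). Interferon-gamma genes were lower in 10 of 11 (median -0.94; adjusted p = 0.724 with an estimated correlation), but without WT replicate 3 their median was -0.16 and without Lin28bKO replicate 3 it was -0.58, and the list was called in neither fit. Single genes called by edgeR numbered 0 of 10089, with 311 at an unadjusted p below 0.05 and 7.92% without overlap (chance gives 10%), and DESeq2 called 2.

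Plasma cell-like cells, 38 to 95 per library, had less Ccr10, a homing receptor, at 47.5 ± 14.1 and 12.5 ± 1.92 CPM, and less Fgl2 at 69.2 ± 2.98 and 27.7 ± 5.53. The interferon-gamma list was not called here (9 of 11 lower, median -0.28, adjusted p = 0.116), and without WT replicate 3 the median turned to 0.08, with 4 of 11 lower. Arhgap5, Plec and Hbegf averaged 27.4, 92.7 and 16.8 CPM in WT and 102, 205 and 45.1 in Lin28bKO, each with an adjusted p = 0.389 and each above 200 CPM in tumour-like cells. EdgeR called 0 of 5504 genes, with 461 at an unadjusted p below 0.05 and 14.6% without overlap (chance gives 10%). DESeq2 called 3, and edgeR called 1 without WT replicate 2 and 3 without WT replicate 3.

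Unnamed cluster 19, whose leading genes Timp3, Dcn, Wnt4 and Ptgis mark stromal cells, had Cxcl9 at 70.8 ± 11.4 and 9.58 ± 10.5 CPM. Its cytokine Il6 was at 69.3 ± 10.1 and 21.2 ± 13.1 CPM, and Bst2, an antiviral tether, at 614 ± 292 and 220 ± 67.4. All 16 interferon-gamma genes measured there were lower (median -0.97; adjusted p = 0.678 with an estimated correlation), and 3 passed adjusted over the list alone. Without Lin28bKO replicate 3 their median was -0.49 and without WT replicate 3 it was -0.58, both still called. Ifi205, Hcar2, Lgr6 and Phgdh had fold changes of -1.39, -2.61, 2.29 and 1.06. Unnamed cluster 12, a low-UMI group with a median of 1360 to 3176.5 UMIs, had lower Gbp2 (-2.04), Cxcl9 (-2.86), Ubd (-2.51), Grcc10 (-0.81) and Rps10-ps1 (-0.90). EdgeR called 0 of 11210 genes in cluster 19 and 0 of 10426 in cluster 12, with 348 and 453 at an unadjusted p below 0.05 and 8.21% and 9.38% without overlap (chance gives 10%), and DESeq2 called 2 and 5. Unnamed cluster 7, mostly from Lin28bKO replicate 1, had Saa3 at 179 ± 20.7 and 33.4 ± 18.8 CPM, Wfdc17 at 430 ± 165 and 116 ± 21.5 and Mki67 at 27.7 ± 14.7 and 89.4 ± 23.3. AW112010 and Cenpe had fold changes of -2.20 and 1.62 there. EdgeR called 0 of its 4785 genes, with 94 at an unadjusted p below 0.05 and 8.19% without overlap (chance gives 10%), and DESeq2 called 2.

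Lin28b acts through let-7, so 28 let-7 target genes were compared. Camera called the list in 0 of the 9 groups tested, with medians from -0.02 in tumour-like cells to 0.20 in fibroblast-like cells. In macrophage-like cells 15 of 25 were higher, and in T cell-like cells 14 of 20. Adjusted over the list alone, the oncofetal RNA-binding protein gene Igf2bp1 passed in neutrophil-like cells (1.81) and the cyclin gene Ccnd2 in cDC-like cells (-0.80).

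Whether the genotype effect differed between classes was tested in the 3 largest, which were the tumour-like class, the macrophage-like class and cluster 12, and in pairs with neutrophil-like cells, the next in size. Between tumour-like and neutrophil-like cells edgeR called 524 of 16736 genes, of which 377 had a lower effect in neutrophil-like cells. Between macrophage-like and neutrophil-like cells it called 19 of 12938. Between tumour-like and macrophage-like cells it called 0 of 17741, with 1587 at an unadjusted p below 0.05, and limma called 0 as well. It called 6 of 16410 between tumour-like cells and cluster 12, and 0 of 12851 between macrophage-like cells and cluster 12, with 1177 at an unadjusted p below 0.05 and 0 by limma. When only genes that passed the filter in both classes were used, the 524 became 4, and the 19 and the 6 became 0, and limma on the difference per mouse called 0 in all 3.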

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

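The tests of explanations in this part were chosen after the result was seen, as were the pairs with neutrophil-like cells, while the interaction test of the 3 largest classes and the fits on immune cells alone and with each library left out had been planned. An interaction test of the genotype effect called 524 genes between tumour-like and neutrophil-like cells, 19 between macrophage-like and neutrophil-like cells and 6 between tumour-like cells and cluster 12. With genes that passed the filter in both classes the counts were 4, 0 and 0, and with limma 0 in each. The fit behind the 524 took the spread of each gene from genes of like abundance, without an estimate of its own. In simulated data without any difference these fits made 16, 15 and 6 false calls, and 0, 0 and 2 with genes that passed in both classes. The 10 splits of 6 samples are too few for a share under 0.05. The highest other split gave 42 genes against the 524, 20 against the 19 and 118 against the 6, and 1, 2 and 4 of the 10 splits gave as many as the real one. The real count was 0 between tumour-like and macrophage-like cells and between macrophage-like cells and cluster 12, where the highest other splits gave 3 and 2, so 10 of 10 splits gave as many.

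Neutrophil-like cells had a lower share in Lin28bKO (fold change -2.40). A lowest UMI count that differs between libraries would, at like depth per cell, end the difference under a common floor of 2200 UMIs. There the fold change was -3.98 (SE 1.01). Over all kept cells the neutrophil-like medians were 1571.5, 2786 and 2024 UMIs in WT and 2552, 1665 and 1398 in Lin28bKO. That floor thus cut the class unequally between libraries. It also came with a new clustering, so it does not decide whether the lowest UMI count was the cause. Depth per cell differed along with that lowest count. Under a floor relative to each library's macrophage-like cells the fold change was -1.71 (SE 1.00) and the groups overlapped. A joint difference in depth and lowest count thus cannot be told apart from fewer neutrophils with these 6 libraries. More tumour cells among the barcodes would lower every immune share, and among immune cells alone the fold change was -1.38 with overlap, which leaves this open too. Without WT replicate 3, which alone lacked Y-linked transcripts, the fold change was -2.28 (edgeR adjusted p = 0.743). Host sex would leave no difference among the libraries left, which all had these transcripts. Their shares did not overlap, at 11.1 and 19.9% in WT and 0.352, 2.93 and 6.27% in Lin28bKO. With so few WT libraries left, and short of the edgeR threshold, these shares do not decide whether host sex set the difference. The sex and the genotype of the hosts both stay open.

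Interferon-gamma response genes were lower in tumour-like, macrophage-like, neutrophil-like and cDC-like cells of Lin28bKO. Free RNA from immune cells could carry such a difference into tumour-like cells, but it would give at most 6.40% of the list's summed CPM there in any library, which argues against it for the sum, while it would give 70.3% of Ciita, 34.1% of Cd274 and 29.1% of Cxcl9 in WT, which leaves these 3 open. A single library is a candidate explanation: without WT replicate 3 the median in tumour-like cells was -0.52 instead of -1.19, which is consistent with that library setting most of the difference there. The medians closest to 0 with 1 library left out were -0.66 in macrophage-like cells, -1.04 in neutrophil-like cells and -0.56 in cDC-like cells, which do not decide it. With the Y-linked sum as a covariate the medians were -0.62 in tumour-like, -0.74 in macrophage-like, -1.15 in neutrophil-like and -1.03 in cDC-like cells. Only WT replicate 3 lacked these transcripts, so sex is tied to that library. Without that library the cDC-like median was -0.99, with 15 of 15 genes lower, against -1.03 over all libraries. The cDC-like median thus did not rest on that library. It moved to -0.56 without WT replicate 1, and camera with an estimated correlation did not call the list. In all of these classes the sex and genotype of the hosts stay open.

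Tumour-cell transcripts took a larger share of UMIs in immune classes of Lin28bKO. Droplets with a tumour cell beside an immune cell would put the excess in few cells, but without the 10% of cells with the most the lowest ratio over 4 classes was still 1.49, which argues against them as the whole cause. A like amount of free RNA spread over fewer UMIs per cell would leave the UMIs of these genes per cell equal, and their ratio was 0.938 in cDC-like cells, which fits this explanation, while 0.942 in macrophage-like, 1.87 in neutrophil-like and 1.31 in T cell-like cells could go either way given the spread between mice. All UMIs per cell averaged 2385 ± 775 in WT and 2228 ± 556 in Lin28bKO in neutrophil-like cells, a ratio of 0.934 beside the 1.98-fold share, so fewer UMIs per cell leave most of it open there. No biological explanation was tested.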

How the results depend on the processing

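The floors on UMIs, the denominator without unnamed clusters, and the comparisons between classes without Lin28bKO replicate 1, on genes that passed in both classes, by limma and with neutrophil-like cells were added after seeing the data. EdgeR's count of 0 genes stayed 0 in every class with the size factors of DESeq2, the replicate block and the Y-linked covariate. It also stayed 0 wherever they were run with doublets kept, the stricter cell filter, the common floor and Leiden resolutions 0.5 and 2.0, which were not run in clusters 7, 12 and 19, and with other classes' markers left out, not run for the whole tumour. With DESeq2 it became 447 in the whole tumour, 157 in macrophage-like, 179 in neutrophil-like, 15 in T cell-like, 3 in plasma cell-like, 2 in cDC-like, 2 in fibroblast-like and 1 in tumour-like cells, 5 in cluster 12, 2 in cluster 19 and 2 in cluster 7. In the simulated data DESeq2 made 52 false calls among 140 in the whole tumour, but the cause was not tested further. Without a filter on low counts edgeR called 490 in macrophage-like, 639 in neutrophil-like, 154 in plasma cell-like, 111 in T cell-like and 79 in cDC-like cells, 135 in cluster 12, 18 in cluster 19 and 46 in cluster 7; the cause was not tested. With 1 library left out the counts ran from 0 to 6 in the whole tumour (without WT replicate 1), 0 to 66 in macrophage-like (without Lin28bKO replicate 2), 0 to 1 in neutrophil-like (without WT replicate 1), 0 to 6 in T cell-like (without Lin28bKO replicate 1), 0 to 2 in cDC-like (without WT replicate 2), 0 to 3 in plasma cell-like cells (without WT replicate 3) and 0 to 1 in cluster 7 (without WT replicate 2); the cause was not tested. Replicate numbers did not pair the samples (WT and Lin28bKO replicate 2 correlated at -0.49 in the whole tumour), and with them as a block camera called 110 lists. Camera's 108 lists of 240 became 98 to 117 with 1 library left out, 109 with doublets kept and 94 with the common floor, but 0 with an estimated correlation and 0 with fry, where the interferon-gamma medians stay -1.42 in the whole tumour, -1.19 in tumour-like, -1.06 in macrophage-like, -1.58 in neutrophil-like and -1.03 in cDC-like cells by construction. The fold change of the neutrophil-like share kept its direction in all alternatives, from -1.38 to -3.98, and stayed short of the threshold in each. The share itself moved with the clustering. It was 8.42% in WT and 2.30% in Lin28bKO at Leiden resolution 2.0, and 9.35% and 2.20% with doublets kept. The macrophage-like share turned to 0.30 among immune cells alone, a denominator without tumour cells, and kept its direction in the other alternatives, as the tumour-like and regulatory T-like shares did in all. The interaction counts moved from 19 to 91 and from 6 to 1 with the size factors of DESeq2, and to 3 and 28 without Lin28bKO replicate 1; with genes that passed in both classes the 524, 19 and 6 became 4, 0 and 0, and with limma 0, and beyond the fewer genes tested the cause was not tested. With doublets kept S100a4, scaled by the UMI total alone, averaged 463 and 284 CPM in macrophage-like cells and 595 and 431 in T cell-like cells of WT and Lin28bKO. The values given before are TMM-scaled, and the clustering with doublets kept gave no natural killer-like class. The scale and, for T cell-like cells, the class thus differ, and the cause was not tested. Of 91 named genes in their classes, 90 kept their direction in every setting, and S100a4 in tumour-like cells ran from -0.34 without WT replicate 3 to 0.10 without WT replicate 2; the cause was not tested. Lin28b is not covered by that count, and its direction rests on single libraries. In the whole tumour it was at 5.11, 2.58 and 3.53 CPM in Lin28bKO replicates 1, 2 and 3. The WT replicates were at 2.52, 3.32 and 4.24 CPM. Over 1414 combinations of gene and setting, 105 passed the threshold that the reported value does not. Depth limits Lin28b in host classes and the classes with few cells, such as the 43 neutrophil-like cells of Lin28bKO replicate 1.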

Other observations

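The tests of hypotheses in this part were chosen after the result was seen, while the gene lists and splits had been planned. MHC class I presentation genes were lower by camera in all 9 groups tested, with medians of -0.61 in the whole tumour (17 of 17), -0.86 in neutrophil-like (17 of 17, 6 passed adjusted over the list alone), -0.60 in fibroblast-like, -0.49 in cluster 19, -0.37 in cDC-like, -0.34 in T cell-like and -0.28 in plasma cell-like cells (adjusted p = 0.678 with an estimated correlation, 0.731 in fibroblast-like cells). Type I interferon response genes were called lower in 8 of the 9, with the lowest median in neutrophil-like cells (-1.28, 18 of 18, adjusted p = 0.686 with an estimated correlation), and not in plasma cell-like cells. MHC class II genes were called lower in the whole tumour (14 of 14, median -0.68), cDC-like cells (13 of 14, -0.19) and cluster 19 (8 of 10, -0.53), with adjusted p = 0.678, 0.678 and 0.724 with an estimated correlation. Ribosomal protein genes were called lower in 8 groups, such as tumour-like cells (75 of 76, median -0.25; adjusted p = 0.678 with an estimated correlation), and higher in neutrophil-like cells (69 of 76, 0.44; adjusted p = 0.743 with an estimated correlation). Oxidative phosphorylation genes were higher in neutrophil-like cells (28 of 35, 0.27; adjusted p = 0.774 with an estimated correlation) and lower in fibroblast-like cells (31 of 35, -0.16; 0.724), plasma cell-like cells (31 of 35, -0.26; 0.678) and cDC-like cells (28 of 35, -0.12; 0.797).

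Other myeloid and stromal programs were called in fewer groups. Lipid-associated macrophage genes were lower in neutrophil-like cells (9 of 11, median -0.77, 5 passed adjusted over the list alone; adjusted p = 0.678 with an estimated correlation) and in the whole tumour (12 of 14, -0.29), higher in plasma cell-like (9 of 11, 0.34) and T cell-like cells (7 of 10, 0.37), and not called in macrophage-like cells (8 of 14 lower, -0.20). Each of the 4 calls had an adjusted p = 0.678 with an estimated correlation. Alternatively activated macrophage genes were lower in the whole tumour (12 of 15, -0.67) and in cDC-like cells (7 of 8, -0.44), each with an adjusted p = 0.678 with an estimated correlation, and were not called in macrophage-like cells (8 of 15 higher, 0.03). Chemokines were lower in the whole tumour (17 of 22, -1.01), in neutrophil-like (15 of 17, -0.61), cDC-like (12 of 17, -0.28) and fibroblast-like cells (13 of 18, -0.42), each with an adjusted p = 0.678 with an estimated correlation, and in cluster 19 (13 of 19, -0.33; adjusted p = 0.696 with an estimated correlation). Immediate early and heat shock genes were called lower in neutrophil-like cells (18 of 20, -0.47; adjusted p = 0.678 with an estimated correlation) and were not called in the whole tumour (15 of 20 lower, adjusted p = 0.0502). Immature neutrophil genes were lower in the whole tumour (11 of 14, -0.96; adjusted p = 0.725 with an estimated correlation) and in macrophage-like cells (11 of 11, -0.79; adjusted p = 0.686 with an estimated correlation), and were not called in neutrophil-like cells (12 of 13 higher, 0.38). Endothelial activation genes were lower in the whole tumour (7 of 9, -0.29) and in macrophage-like cells (6 of 7, -0.96), each with an adjusted p = 0.678 with an estimated correlation, a list that shares Cxcl9 and Cxcl10 with the interferon-gamma list. Angiogenic endothelial genes were higher in tumour-like cells (10 of 11, 0.12; adjusted p = 0.678 with an estimated correlation). Epithelial-mesenchymal transition genes were higher in macrophage-like cells (10 of 15, 0.35) and plasma cell-like cells (8 of 8, 0.72), with adjusted p = 0.678 with an estimated correlation, where tumour-cell transcripts were higher too. Antigen-presenting fibroblast genes were lower in the whole tumour (7 of 10, -0.68; adjusted p = 0.678 with an estimated correlation) and were not called in fibroblast-like cells (5 of 9 lower, -0.04). Lin28a, the paralog of Lin28b, gave 93 of its 108 UMIs in WT and 27 of 50 in Lin28bKO in neutrophil-like cells. Per UMI of that class it was at 6.67, 8.80 and 5.41 CPM in WT and 24.9, 11.1 and 15.8 in Lin28bKO (fold change 0.73, edgeR adjusted p = 0.238). The 24.9 CPM rested on 3 UMIs, with a 95% interval of 5.14 to 72.8. The fold change comes from the fit with TMM scaling, and these CPM are scaled by the UMI total alone.

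The 10 splits of 6 samples are too few for a share under 0.05. EdgeR called 0 genes in each class with the real groups, so 10 of 10 splits gave as many. The highest other split called 334 genes in the whole tumour, 912 in tumour-like, 1019 in fibroblast-like, 145 in cDC-like, 17 in macrophage-like, 17 in T cell-like, 14 in neutrophil-like and 7 in plasma cell-like cells, 2 in cluster 12, 3 in cluster 19 and 275 in cluster 7. The counts in the whole tumour, tumour-like, fibroblast-like and cDC-like cells came from the split that sets WT replicates 1 and 3 with Lin28bKO replicate 2, a structure other than the genotype. These libraries had the most acinar enzyme transcripts in the whole tumour (5360, 3944 and 1851 CPM against 164 to 640 in the others). Whether acinar content explains the counts was not tested. In cluster 7 the highest split set WT replicates 1 and 3 with Lin28bKO replicate 3. Camera called 108 lists with the real groups, 1 of 10 splits gave as many, and the highest other split gave 107. For shares of classes and of lymphocyte groups, 0 passed with the real groups and 1 in the highest other split.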
